A study of Drosophila melanogaster with 12 samples.

How the data were processed

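The values analysed were microarray intensities, 1 per probe set and array, as deposited for 12 Affymetrix Drosophila 2.0 arrays hybridised in 1 colour from 100 ng of RNA each. They were on a linear scale, with 9.45% to 13.7% of values per array below 0 and array medians from 39.3 to 95.6, so the arrays had not been brought to a common scale. The program that summarised probes, the subtraction of background or mismatch signal and any scaling by the authors are not given in the sources used here. No pair of arrays had identical values (0 pairs). Of 18869 probe sets, 100 controls were left out. Symbols came from the platform annotation, in which 13647 probe sets had 1 symbol, 402 had several and 4720 had none. Of those with 1 symbol, 13544 matched the gene table supplied, and probe sets with several or no symbols were tested but not named. No per-sample column was left unused (0 columns).

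The plan made before the data were examined took the values as deposited as already normalized. Since they were not, quantile normalization over all 12 arrays was used, and the values as deposited and median centring became the alternatives. Normalized values were floored at 0 and put on the scale of log2(value + 1). The 40% of probe sets with the lowest mean over all arrays (below a mean intensity of 23.6) were left out, which left 11262, of which 10042 had 1 symbol, for 9495 genes. A probe set was at background in a group when in no array above that array's 95th percentile of control probe sets. These percentiles were 12.7 to 27.5 as deposited and 13.7 to 24.6 normalized. This rule was added after the data were seen. A fold against such a group is given as a bound, the mean of the brighter group over that percentile.

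One linear model with a mean for each of the 4 groups (8 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend. P values were adjusted by Benjamini-Hochberg over the probe sets of each of 6 contrasts, and an adjusted p under 0.05 was a call. Every adjusted p of a gene is from limma and two-sided. The translational index was the high minus the low fraction, its change the difference of the indices between diets, and the averaged diet difference gave both fractions equal weight. SE is that of limma, and SD is over the 3 arrays of a group or the 3 gradients of a diet. The named genes were the 10 with the largest rise and the 10 with the largest fall per contrast among those called whose replicates did not overlap (chance gives 10% for 3 against 3), up to 4 members of smallest p of each called list, and 6 insulin and TOR genes. Where a gene had several probe sets the brightest stood for it in lists. Of 44 named results with another probe set, all probe sets had the same sign in 40.

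Of 34 gene lists written from general knowledge before the data were examined, 31 had at least 5 measured genes and were tested with camera (preset correlation 0.01), with adjustment over the lists of a contrast. The lists respiratory complex II, female germline and yolk, and mitochondrially encoded genes had fewer and are not analysed here, and 89 list entries matched no probe set. After the data were seen Mdh1, CG4849, Cyp1, Cyp40 and Acp65Aa were taken out of lists for their identity, not their values. Camera with an estimated correlation and fry were run beside it. For members of a list the adjusted p over all genes decides, and the count adjusted over the list alone is given beside it.

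The replicate number was read from the sample titles, in which the first replicate of 4% YE has none. A gradient is a diet with a number. Arrays of 1 number correlated in their departures from group means (0.166 to 0.669 in all 12 direct pairs), best in 26 of 36 comparisons. Numbers 2 and 3 also correlated with each other, so their pairing into gradients is not shown. What the number stands for is not given. It was not a block in the main model, as planned, and is given as one where it changed a call or moved a count by more than 1.5 times. Log2 intensities of replicates 2 and 3 correlated at 0.979 to 0.988 within groups and those of replicate 1 with them at 0.859 to 0.943.

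The procedure was tested on simulated data with 100 probe sets changed per contrast. For the index on 4% YE it recovered 30 at 2-fold and 86 at 4-fold, for that on 0.25% YE 18 and 80, for the index change 3 and 43, for the diet difference in the high fraction 29 and 85, in the low fraction 32 and 79 and averaged 63 and 95. Among unchanged probe sets 0 to 8 per contrast were called. Camera called 10 of 10 lists of 30 genes shifted by 0.5 log2 per contrast, also with an estimated correlation. Of 10 unshifted lists it called 0 or 1, but this does not cover correlated genes. Without gene models the planned correlation of index and transcript length was not run and genome positions are not given.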

Results

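Adult male w1118 flies, a white-eyed laboratory strain of Drosophila melanogaster, were kept for 6 days on food with 4% or with 0.25% yeast extract (YE), the main protein source of the diet. Lowering the yeast is a common form of dietary restriction in this species. Extracts were separated on sucrose gradients, and RNA was taken from a low fraction (mRNAs with 1 to 4 ribosomes) and a high fraction (5 or more ribosomes). Each of the 4 groups of diet and fraction had 3 biological replicates, which gave 12 arrays from 6 gradients, 3 per diet. The translational index of an mRNA is its log2 level in the high fraction minus that in the low fraction. The arrays carried 18769 probe sets other than controls, and 11262 of these, naming 9495 genes, were bright enough to test. Between 59.0% and 66.4% of probe sets per array exceeded the background, and the number of arrays, 3 per group, limited the precision. Values below are group means with standard deviation (SD) or log2 differences with standard error (SE), n = 3 per group.

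The first comparison was of the high with the low fraction on 4% YE, the rich diet, which after normalization ranks mRNAs only against each other. mRNAs of ribosomal proteins and of the respiratory chain lay toward the low fraction. Of the 41 measured cytosolic ribosomal protein mRNAs, 32 were lower in the high fraction, 0 were higher and 9 were not called, with a median index of -0.76 (adjusted p = 2.6e-10, and adjusted p = 0.27 with an estimated correlation). RpL41, the smallest ribosomal protein, measured 5100 ± 283 in the high and 8240 ± 451 in the low fraction (index -0.69 ± 0.10, adjusted p = 0.00049). Among the 27 subunits of respiratory complex I, the NADH dehydrogenase, 20 were lower, 3 were higher and 4 were not called, with a median of -1.04 (adjusted p = 9.1e-07, and adjusted p = 0.28 with an estimated correlation). Its subunit ND-MNLL measured 932 ± 149 in the high and 3460 ± 95.2 in the low fraction (index -1.90 ± 0.18, adjusted p = 0.00012).

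Toward the high fraction lay mRNAs of protein breakdown, amino acid activation and lipid storage. In the proteasome, the protease that degrades ubiquitin-tagged proteins, 19 of 38 mRNAs were higher, 3 were lower and 16 were not called (median 0.77, adjusted p = 0.00028, and adjusted p = 0.35 with an estimated correlation). The regulatory subunit Rpn3 measured 1340 ± 137 in the high and 408 ± 69.1 in the low fraction (index 1.72 ± 0.23, adjusted p = 0.00038). Of the 29 aminoacyl-tRNA synthetase mRNAs, whose enzymes charge tRNAs with amino acids, 13 were higher, 0 were lower and 16 were not called (median 0.70, adjusted p = 3.4e-05, and adjusted p = 0.28 with an estimated correlation). Of 13 lipid synthesis and storage mRNAs, 7 were higher and 6 were not called (median 0.68, adjusted p = 0.00085, and adjusted p = 0.27 with an estimated correlation), among them the fatty acid desaturase Desat1 at 1.04 ± 0.12 and the lipid droplet protein Lsd-1 at 1.46 ± 0.31. Catalase (Cat), which breaks down hydrogen peroxide, measured 4110 ± 270 in the high and 1140 ± 89.9 in the low fraction (index 1.85 ± 0.17, adjusted p = 0.00011).

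Other mitochondrial lists also lay toward the low fraction. All but 1 of the 8 cytochrome c oxidase (complex IV) mRNAs were lower (median -0.81, adjusted p = 3.4e-05, and adjusted p = 0.27 with an estimated correlation). Among these were COX7C at -1.23 ± 0.14 and COX8 at -1.30 ± 0.16. In the mitochondrial protein import list 10 of 12 mRNAs were lower and 2 were not called (median -0.98, adjusted p = 0.00011, and adjusted p = 0.27 with an estimated correlation), among them Tom7 at -1.48 ± 0.17 and Tim8 at -1.58 ± 0.21. Of 71 mitochondrial ribosomal protein mRNAs, 26 were lower, 5 were higher and 40 were not called (median -0.39, adjusted p = 0.0054, and adjusted p = 0.64 with an estimated correlation). Complex III and cytochrome c had 4 of 7 mRNAs lower and 3 not called (median -0.56, adjusted p = 0.0059, and adjusted p = 0.28 with an estimated correlation). The ATP synthase list had 7 of 13 lower, 3 higher and 3 not called (median -0.38, adjusted p = 0.033, and adjusted p = 0.41 with an estimated correlation), and its call was lost with the replicate number as a block (adjusted p = 0.066, range over its alternatives 0.0044 to 0.54). The mitochondrial ribosomal median was -0.21 and -0.25 without high-fraction 4% YE replicates 2 and 3.

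Accessory gland and noncoding transcripts lay toward the low fraction. Of the 22 accessory gland and seminal fluid mRNAs, 16 were lower in the high fraction, 1 was higher and 5 were not called (median -1.10, adjusted p = 3.4e-05, and adjusted p = 0.29 with an estimated correlation). The sex peptide mRNA SP, whose product changes female behaviour after mating, had an index of -1.62 ± 0.27 (adjusted p = 0.001). Of 30 long noncoding RNAs, 13 were lower and 17 were not called (median -0.99, adjusted p = 8.4e-05, and adjusted p = 0.29 with an estimated correlation), led by pncr003:2L at -2.48 ± 0.35. The transcript pncr003:2L is annotated as noncoding but is known to encode the short sarcolamban peptides of muscle.

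Metabolic and photoreceptor lists lay toward the high fraction. Fatty acid oxidation had 6 of 9 mRNAs higher, 1 lower and 2 not called (median 0.94, adjusted p = 0.0059, and adjusted p = 0.27 with an estimated correlation). Members included yip2, a thiolase, at 1.90 ± 0.36. Glycolysis had 5 of 9 higher and 4 not called (median 0.47, adjusted p = 0.0043, and adjusted p = 0.27 with an estimated correlation). Among these was Pgk at 1.17 ± 0.18. Cytochrome P450s, enzymes that oxidise toxins and hormones, had 24 of 72 higher, 3 lower and 45 not called (median 0.42, adjusted p = 0.0024, and adjusted p = 0.41 with an estimated correlation). Members included Cyp12c1 at 1.40 ± 0.23. Photoreceptor mRNAs had 7 of 12 higher and 5 not called (median 0.81, adjusted p = 0.0059, and adjusted p = 0.27 with an estimated correlation). Among these was the eye protein kinase C inaC at 1.94 ± 0.20. The citric acid cycle list had 3 of 9 higher and 6 not called (median 0.52, adjusted p = 0.04, and adjusted p = 0.29 with an estimated correlation). Members included ScsbetaG at 1.92 ± 0.29. The antioxidant list had 3 of 12 higher, 1 lower and 8 not called (median 0.56, adjusted p = 0.044, and adjusted p = 0.29 with an estimated correlation), and Trx2, a thioredoxin, was its member on the low side at -1.22 ± 0.17. The last 2 calls were lost with the replicate number as a block (adjusted p = 0.057 and 0.068, ranges over their alternatives 0.021 to 0.36 and 0.028 to 0.31), without high-fraction 4% YE replicate 1 (0.0785 and 0.0722) and without low-fraction 4% YE replicate 1 (0.0528 and 0.0881). The P450 median was 0.27 without low-fraction 4% YE replicate 2. The citric acid cycle median was 0.18 without high-fraction 4% YE replicate 1 and 0.34 without low-fraction 4% YE replicate 1.

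Of the insulin and TOR genes fixed for naming, S6k, a kinase that acts on ribosomes, had an index of 1.5 ± 0.35 (adjusted p = 0.0059) and the insulin receptor InR one of 1.07 ± 0.29 (adjusted p = 0.013). The InR call was lost without low-fraction 4% YE replicate 2 (0.054) or 3 (0.059), with adjusted p from 3.8e-06 to 0.059 over its alternatives. The indices of the transcription factor foxo, 0.50 ± 0.47 (adjusted p = 0.44), and of the cap-binding protein eIF4E1, -0.14 ± 0.17 (adjusted p = 0.56), were not called. Thor and Tor are unnamed here. Lists that were not called on 4% YE were heat shock proteins (adjusted p = 0.066), neuron (0.066), haemocyte (0.066), testis (0.11), insulin and TOR signalling (0.11), antimicrobial peptides (0.18), digestive enzymes (0.45), fat body (0.46), circadian clock (0.47), glutathione S-transferases (0.51), translation elongation and release factors (0.66), translation initiation factors (0.83) and muscle (0.97).

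In all, 1831 probe sets were higher and 2015 lower in the high fraction on 4% YE, and 5016 had an unadjusted p under 0.05 where chance gives 563. Of the 20 named genes with the largest indices, 13 had a group at background, where only a bound holds. The Y-linked ORY was at least 5.35-fold higher in the high fraction, and CG3746 was at least 2.31-fold lower. Measured on both sides, CG32984 had an index of 3.21 ± 0.64. Adjusted over the list alone, 33 ribosomal protein, 22 complex I, 7 complex IV, 10 import, 26 mitochondrial ribosomal, 4 complex III, 7 ATP synthase, 17 accessory gland and 13 noncoding transcripts were lower, and 19 proteasome, 16 synthetase, 7 lipid, 7 fatty acid oxidation, 6 glycolysis, 25 P450, 7 photoreceptor, 3 citric acid cycle and 5 antioxidant mRNAs were higher. None of the 18 list calls held with an estimated correlation (0 at an adjusted p under 0.05 by camera, 5 of 31 lists at an unadjusted p under 0.05), whereas fry called 23 lists. With the values as deposited the median of all probe sets was 0.32 log2 higher in the high fraction, and the calls split 1865 higher and 538 lower (77.6% higher against 47.6%). No called list changed direction under that scaling.

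**Figure D1:**
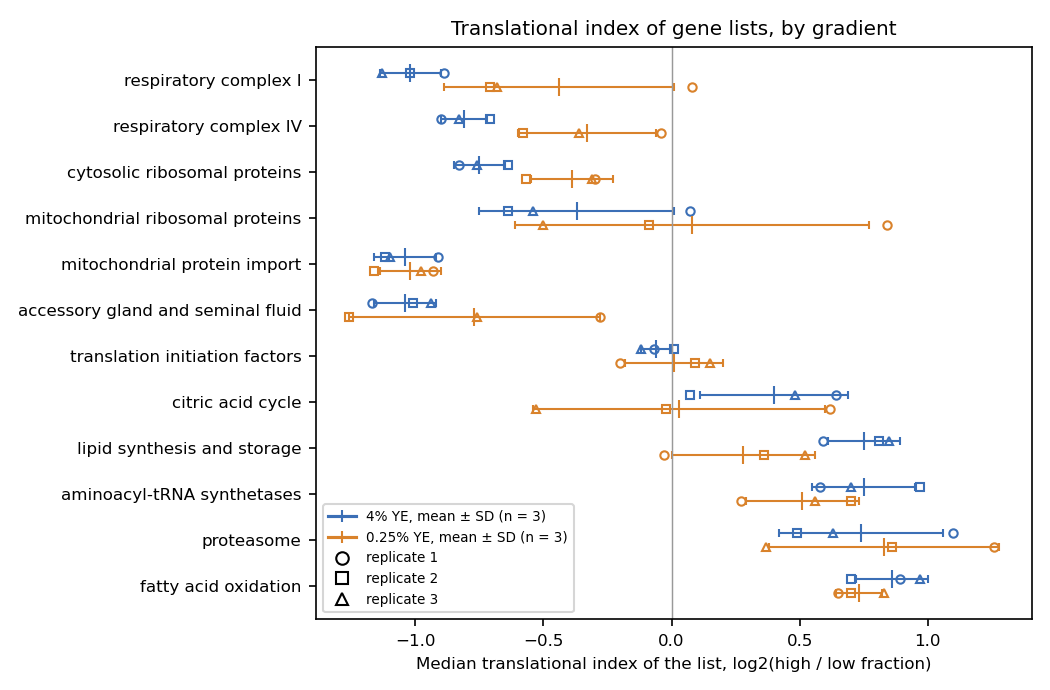
Median translational index (x axis, log2 of high over low fraction) of 12 gene lists (y axis) in each gradient, with circles, squares and triangles for replicates 1, 2 and 3, vertical bars for the mean and horizontal bars for SD (n = 3 gradients per diet). Complex I averaged -1.02 ± 0.12 on 4% YE and -0.44 ± 0.45 on 0.25% YE, where replicate 1 lay apart at 0.08.

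The same comparison on 0.25% YE, the restricted diet, called 16 lists, 15 of which were also called on 4% YE in the same direction. Of the 41 cytosolic ribosomal protein mRNAs 17 were lower in the high fraction, 1 was higher and 23 were not called (median -0.42, adjusted p = 6.2e-06, and adjusted p = 0.34 with an estimated correlation), and RpL41 had an index of -0.62 ± 0.10. Accessory gland mRNAs had 13 of 22 lower, 1 higher and 8 not called (median -0.86, adjusted p = 6e-06, and adjusted p = 0.34 with an estimated correlation). Among these was SP at -1.55 ± 0.27. Noncoding RNAs had 10 of 30 lower and 20 not called (median -0.86, adjusted p = 6e-06, and adjusted p = 0.34 with an estimated correlation). Members included pncr003:2L at -2.73 ± 0.35. The proteasome had 18 of 38 higher, 2 lower and 18 not called (median 0.67, adjusted p = 1.3e-05, and adjusted p = 0.34 with an estimated correlation). Among these were Rpn3 at 1.69 ± 0.23 and the testis-specific paralog Prosalpha4T2 at -1.70 ± 0.30.

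Mitochondrial import mRNAs had 7 of 12 lower and 5 not called (median -0.98, adjusted p = 4.5e-05, and adjusted p = 0.34 with an estimated correlation). Members included Tom7 at -1.34 ± 0.17. Complex I had 11 of 27 lower, 3 higher and 13 not called (median -0.39, adjusted p = 0.0094, and adjusted p = 0.54 with an estimated correlation). Among these were ND-MNLL at -1.53 ± 0.18 and ND-51, a matrix-side subunit, at 0.78 ± 0.17. The ND-51 call was lost without high-fraction 0.25% YE replicate 2 (0.055). Complex IV had 4 of 8 lower (median -0.40, adjusted p = 0.011, and adjusted p = 0.46 with an estimated correlation). Members included COX8 at -0.85 ± 0.16. Complex III and cytochrome c had 3 of 7 lower (median -0.26, adjusted p = 0.017, and adjusted p = 0.34 with an estimated correlation). Testis mRNAs had 8 of 32 lower, 2 higher and 22 not called (median -0.53, adjusted p = 0.0071, and adjusted p = 0.47 with an estimated correlation). Among these was the sperm-tail protein mRNA Mst84Dc at -1.15 ± 0.19. The complex I call was lost without low-fraction 0.25% YE replicate 3 (adjusted p = 0.0519, range over its alternatives 0.00012 to 0.67) and the testis call without high-fraction 0.25% YE replicate 1 (adjusted p = 0.0576, range 0.00092 to 0.66). The complex I median was -0.65 and -0.26 without high-fraction 0.25% YE replicates 1 and 3. The complex III median was -0.49 and -0.47 without high-fraction 0.25% YE replicates 1 and 3. The testis median was -0.35 without low-fraction 0.25% YE replicate 1.

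On the high side, synthetases had 7 of 29 mRNAs higher and 22 not called (median 0.48, adjusted p = 0.0014, and adjusted p = 0.42 with an estimated correlation). P450s had 12 of 72 higher, 3 lower and 57 not called (median 0.29, adjusted p = 0.0077, and adjusted p = 0.54 with an estimated correlation). Members included Cyp313a1 at 1.61 ± 0.28 and Cyp6a2 at -2.03 ± 0.40. Fatty acid oxidation had 4 of 9 higher (median 0.72, adjusted p = 0.0092, and adjusted p = 0.34 with an estimated correlation). Antioxidant enzymes had 3 of 12 higher (median 0.53, adjusted p = 0.0092, and adjusted p = 0.34 with an estimated correlation). Among these was Cat at 1.17 ± 0.17. Photoreceptor mRNAs had 5 of 12 higher (median 0.55, adjusted p = 0.011, and adjusted p = 0.34 with an estimated correlation). Members included inaC at 1.55 ± 0.20. Lipid synthesis and storage had 4 of 13 higher (median 0.23, adjusted p = 0.042, and adjusted p = 0.34 with an estimated correlation). Among these was Desat1 at 0.49 ± 0.12. The Desat1 call was lost without high-fraction 0.25% YE replicate 2 (0.069) or low-fraction 0.25% YE replicate 2 (0.0504). Glycolysis had 1 of 9 higher (median 0.28, adjusted p = 0.0495, and adjusted p = 0.34 with an estimated correlation). Members included Pgk at 1.03 ± 0.18. The lipid and glycolysis calls were lost with the replicate number as a block (adjusted p = 0.056 and 0.081, ranges over their alternatives 0.0065 to 0.44 and 0.023 to 0.44). The lipid call was also lost without low-fraction 0.25% YE replicate 2 or 3 (0.0556 and 0.131), and the glycolysis call without high-fraction 4% YE replicate 2 (0.0533) or 3 (0.0538), low-fraction 4% YE replicate 1 (0.0647), 2 (0.0544) or 3 (0.0568), high-fraction 0.25% YE replicate 1 (0.0544) or 2 (0.0603) or low-fraction 0.25% YE replicate 2 (0.0556) or 3 (0.127). The lipid median was 0.38 and 0.36 without high-fraction 0.25% YE replicates 1 and 3 and 0.52 and 0.12 without low-fraction 0.25% YE replicates 1 and 3.

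Single transcripts far from 0 on 0.25% YE were CG40467 at 2.88 ± 0.48 and CG11893 at 2.72 ± 0.51 toward the high fraction, and the metallothionein MtnD at -2.69 ± 0.40 and lncRNA:CR33942 at -2.81 ± 0.52 toward the low fraction. Of the 20 with the largest indices, 4 had a group at background. S6k had an index of 1.13 ± 0.35 (adjusted p = 0.037), a call lost without high-fraction 4% YE replicate 2 (0.053) or 3 (0.0504), high-fraction 0.25% YE replicate 2 (0.1) or 3 (0.12) or low-fraction 0.25% YE replicate 1 (0.1). InR, at 0.79 ± 0.29, was not called (adjusted p = 0.069), but was with the replicate number as a block (adjusted p = 0.0049, range over its alternatives 2.1e-06 to 0.18). The calls numbered 1087 higher and 1322 lower, with 4123 at an unadjusted p under 0.05 where chance gives 563, and 1892 and 2040 with the replicate number as a block. The total of 2409 dropped to 752 without high-fraction 0.25% YE replicate 2, to 1120 without high-fraction replicate 3 and to 1261 without low-fraction replicate 2 of that diet. As deposited, 1460 were higher and 123 lower (92.2% higher against 45.1%, with a median of all probe sets of 0.41). With each array centred on its median they were 1386 and 1053 (56.8% higher, median 0.12).

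Adjusted over the list alone on 0.25% YE, 23 ribosomal protein, 16 accessory gland, 15 noncoding, 8 import, 12 complex I, 5 complex IV, 3 complex III and 10 testis transcripts were lower, and 19 proteasome, 9 synthetase, 14 P450, 7 fatty acid oxidation, 4 antioxidant, 6 photoreceptor, 4 lipid and 1 glycolysis mRNAs were higher. None of the 16 list calls held with an estimated correlation (0 by camera, 3 lists at an unadjusted p under 0.05), and fry called 17. The other 15 lists were not called, and among them mitochondrial ribosomal proteins had a median of 0.13 over all 3 gradients and -0.32 in replicates 2 and 3. The 2 diets shared 947 probe sets higher in the high fraction (177 if independent) and 1091 lower (237 if independent), with 0 called in opposite directions. The index correlated between diets across probe sets (r = 0.848), which are not independent replicates. The SD of the index across probe sets was 0.933 ± 0.059 on 4% YE and 0.928 ± 0.09 on 0.25% YE (n = 3 gradients per diet), a difference within the spread between gradients (exact two-sided permutation p = 0.9, with 0.1 the smallest that 3 against 3 can give).

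The comparison at the centre of the design was the change of the index between diets, which asks whose distribution over polysomes shifted on 0.25% YE. Median changes were positive for lists of the respiratory chain and both kinds of ribosome on 0.25% YE. They were negative for lipid storage, the citric acid cycle and heat shock. All were under 0.6 log2 in size, called at the preset correlation only and not by fry, with no single member called. The 27 complex I mRNAs had a median change of 0.52 (adjusted p = 5.2e-12, and adjusted p = 0.17 with an estimated correlation), from a mean list index of -1.02 ± 0.12 (SD, n = 3 gradients) on 4% YE to -0.44 ± 0.45 on 0.25% YE. The 71 mitochondrial ribosomal protein mRNAs changed by 0.46 (adjusted p = 5.2e-12, and adjusted p = 0.52 with an estimated correlation), the 8 complex IV mRNAs by 0.45 (adjusted p = 5e-08, and adjusted p = 0.17 with an estimated correlation), and the 41 cytosolic ribosomal protein mRNAs by 0.30 (adjusted p = 5.9e-10, and adjusted p = 0.24 with an estimated correlation). Examples, none of which was called, were COX5B at 0.54 ± 0.16 (adjusted p = 0.99), ND-13A at 0.67 ± 0.22, mRpL30 at 0.87 ± 0.32 and RpL23 at 0.37 ± 0.15. The complex I median change was 0.34 without high-fraction 0.25% YE replicate 1. The mitochondrial ribosomal median change was 0.25 without low-fraction 0.25% YE replicate 1.

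Toward the low fraction went the 13 lipid synthesis and storage mRNAs (median -0.29, adjusted p = 0.0003, and adjusted p = 0.17 with an estimated correlation). Among these were Desat1 at -0.54 ± 0.17 and the triglyceride lipase bmm at -0.73 ± 0.25. The 9 citric acid cycle mRNAs changed by -0.41 (adjusted p = 0.00092, and adjusted p = 0.17 with an estimated correlation). Members included ScsbetaA at -0.67 ± 0.28. The 15 heat shock protein mRNAs changed by -0.31 (adjusted p = 0.0047, and adjusted p = 0.17 with an estimated correlation). Among these were the chaperones Hsp68 at -0.99 ± 0.35 and DnaJ-1 at -0.66 ± 0.25. The 29 synthetases changed by -0.23 (adjusted p = 0.0048, and adjusted p = 0.65 with an estimated correlation) and the 9 glycolysis mRNAs by -0.17 (adjusted p = 0.0093, and adjusted p = 0.17 with an estimated correlation). Glutathione S-transferases, detoxifying enzymes, changed by 0.52 over 33 mRNAs (adjusted p = 0.00022, and adjusted p = 0.69 with an estimated correlation), the ATP synthase list by 0.35 over 13 (adjusted p = 0.0064, and adjusted p = 0.52 with an estimated correlation) and complex III with cytochrome c by 0.26 over 7 (adjusted p = 0.047, and adjusted p = 0.52 with an estimated correlation). In all 12 lists no member was called over all genes by limma, and adjusted over the list alone 3 complex IV mRNAs and 1 ATP synthase mRNA were. Exchanging gradients between the diets gave up to 12 called lists among the 9 other splits, as many as the real grouping. The lipid median change was -0.14 without low-fraction 0.25% YE replicate 1. The citric acid cycle median change was -0.64 without high-fraction 0.25% YE replicate 1. The heat shock median change was -0.17 and -0.52 without low-fraction 0.25% YE replicates 1 and 3. The synthetase median change was -0.14 and -0.37 without high-fraction 4% YE replicates 1 and 3, -0.38, -0.12 and -0.15 without low-fraction 4% YE replicates 1, 2 and 3 and -0.10 without low-fraction 0.25% YE replicate 1. The ATP synthase median change was 0.21 without low-fraction 0.25% YE replicate 1.

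The 0.25% YE gradient of replicate 1 stood apart, with an index that, across probe sets, correlated at 0.26 to 0.503 with the other 2 gradients of its diet, which correlated at 0.803 with each other. In that gradient the median index was 0.08 for complex I and 0.84 for mitochondrial ribosomal proteins, against -0.71 and -0.68, and -0.09 and -0.50, in replicates 2 and 3. In replicates 2 and 3 alone the medians were 0.33 for complex I, 0.33 for complex IV, 0.28 for mitochondrial and 0.24 for cytosolic ribosomal proteins, 0.23 for glutathione S-transferases, -0.23 for lipid storage, -0.54 for the citric acid cycle and -0.33 for heat shock proteins, each still called. In those replicates the synthetase (-0.18), ATP synthase (0.24), glycolysis (-0.06) and complex III (0.29) lists were not. Without low-fraction 0.25% YE replicate 1 the glutathione S-transferase median was 0.055. Its call and those of ATP synthase and synthetases were then lost (adjusted p = 0.616, 0.063 and 0.063, ranges over their alternatives 7.5e-07 to 0.85, 0.001 to 0.75 and 7.6e-05 to 0.65). Without high-fraction 0.25% YE replicate 1 the ATP synthase and glycolysis calls were lost (0.37 and 0.111, range for glycolysis 0.0026 to 0.37), and without high-fraction 4% YE replicate 1 the synthetase and glycolysis calls (0.121 and 0.0633). The complex III call was lost with the replicate number as a block (adjusted p = 0.095, range 0.0027 to 0.65) and without high-fraction 4% YE replicate 2 (0.0889) or 3 (0.124), low-fraction 4% YE replicate 1 (0.0882) or 2 (0.0892), high-fraction 0.25% YE replicate 1 (0.39) or 3 (0.0674) or low-fraction 0.25% YE replicate 2 (0.0889) or 3 (0.142).

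By probe set, limma called 1 transcript, CG43131 (5.30 ± 0.63, adjusted p = 0.021), whose low fraction on 0.25% YE was at background (means 33.4 and 58 on 4% YE and 30.1 and -4.74 on 0.25% YE), so its size has no firm value. It was 1.38 with log2(value + 32), where it was not called, and the count was 0 with the replicate number or the gradient as a block (922 and 808 probe sets at an unadjusted p under 0.05). The count was also 0 without any 1 of the 6 arrays of 4% YE and without high-fraction 0.25% YE replicate 2 or 3. Without a block 485 probe sets had an unadjusted p under 0.05, and chance gives 563. Replicates 2 and 3 alone gave 7 calls, among them Pdi, a protein disulfide isomerase, with a change of -2.39 ± 0.27 (adjusted p = 0.015, means of 765 and 154 in the high and low fraction on 4% YE and 130 and 135 on 0.25% YE). Over all replicates the Pdi change was -2.58 but was not called (adjusted p = 0.99). Pdi was picked after its values were seen. The indices of InR (-0.28 ± 0.41), foxo (0.17 ± 0.67), S6k (-0.37 ± 0.49) and eIF4E1 (0.09 ± 0.24) differed by less than their SE. With an estimated correlation camera called 0 of the 31 lists (6 at an unadjusted p under 0.05) and fry also called 0 (7 at an unadjusted p under 0.05). The other 19 lists, among them proteasome (median -0.01) and translation initiation factors (0.02), were not called, with adjusted p from 0.15 (testis) to 0.98 (antioxidant enzymes).

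Diet was then compared within each fraction. In the high fraction the falls on 0.25% YE included fat body products, digestive sugar-splitting enzymes and detoxification enzymes. Genes of none of these groups also fell, among them CG34316 at -3.68 ± 0.50 and CG3999 at -2.89 ± 0.31. Lsp2, a storage protein that the fat body secretes (probe set 1641634_at), dropped from 6530 ± 599 to 112 ± 83.1 (-6.38 ± 0.77, adjusted p = 0.0013), and fit, a fat body peptide that responds to dietary protein (1627088_at), from 2630 ± 548 to 278 ± 124 (-3.34 ± 0.59, adjusted p = 0.014). The maltase Mal-A4 (1631806_at) went from 3640 ± 780 to 805 ± 199 (-2.18 ± 0.25, adjusted p = 0.0009), the amylase relative Amyrel changed by -3.17 ± 0.42, and the P450 Cyp309a1 (1626324_at) went from 1000 ± 147 to 159 ± 15.3 (-2.65 ± 0.23, adjusted p = 0.00014). The largest rises were in genes of unknown function: CG13215 (1633066_at) was at least 17.3-fold higher on 0.25% YE (adjusted p = 6.5e-05), and CG13947 (1628376_x_at) went from 486 ± 204 to 3400 ± 1620 (2.77 ± 0.35, adjusted p = 0.0017).

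By list, P450s had 6 of 72 members lower, 0 higher and 66 not called (median -0.37, adjusted p = 9.8e-09, and adjusted p = 0.23 with an estimated correlation, 13 lower adjusted over the list alone). Members included Cyp12d1-d at -1.91 ± 0.26. The 7 fat body mRNAs had 3 lower and 4 not called (median -0.83, adjusted p = 4e-05, and adjusted p = 0.21 with an estimated correlation, 3 lower adjusted over the list alone), and the iron carrier Tsf1 was at -1.05 ± 0.20. Glutathione S-transferases had 2 of 33 lower and 31 not called (median -0.31, adjusted p = 0.00021, and adjusted p = 0.47 with an estimated correlation, 2 lower adjusted over the list alone), with GstD8 at -2.15 ± 0.31 and GstD4 at least 2.59-fold lower. Digestive enzymes had 3 of 30 lower and 27 not called (4 lower adjusted over the list alone), all 3 of them maltases: Mal-A4, Mal-A8 at -1.72 ± 0.30 and Mal-A2 at -1.58 ± 0.34. With each array centred on its median the list median was -0.15. After quantile normalization it was 0.01, the mean -0.40 and the direction of the test down (adjusted p = 0.021, and adjusted p = 0.62 with an estimated correlation). The glutathione S-transferase median was -0.20 without high-fraction 4% YE replicate 1 and -0.48 without high-fraction 0.25% YE replicate 1.

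mRNAs of the respiratory chain rose as lists in the high fraction, by less with each array centred on its median than after quantile normalization. The centred medians were 0.38 for complex I, 0.27 for complex IV, 0.21 for complex III, 0.08 for ATP synthase, 0.33 for mitochondrial import and 0.10 for cytosolic ribosomal proteins. After quantile normalization complex I had 2 of 27 higher and 25 not called (median 0.57, adjusted p = 1.3e-11, and adjusted p = 0.21 with an estimated correlation, 14 higher adjusted over the list alone). Among these was ND-13A at 0.72 ± 0.16. Complex IV had 3 of 8 higher and 5 not called (median 0.53, adjusted p = 7.7e-08, and adjusted p = 0.21 with an estimated correlation, 7 adjusted over the list alone), and COX5B went from 2930 ± 134 to 4620 ± 574 (0.65 ± 0.11, adjusted p = 0.014). Complex III had a median of 0.39 (adjusted p = 0.0018, and adjusted p = 0.23 with an estimated correlation, 3 of 7 higher adjusted over the list alone), ATP synthase 0.29 (adjusted p = 0.0018, and adjusted p = 0.29 with an estimated correlation, 5 of 13) and mitochondrial import 0.40 (adjusted p = 0.0044, and adjusted p = 0.25 with an estimated correlation, 4 of 12). Cytosolic ribosomal proteins had a median of 0.27 (adjusted p = 2.7e-08, and adjusted p = 0.23 with an estimated correlation), and the 1 member of 41 called, RpL24-like at 1.10 ± 0.20, is known as a ribosome assembly factor rather than a ribosomal subunit. Mitochondrial ribosomal proteins had a median of 0.27 (adjusted p = 5.3e-05, and adjusted p = 0.54 with an estimated correlation) with 0 of 71 called by limma. Muscle mRNAs had 2 of 23 higher (median 0.41, adjusted p = 0.0011, and adjusted p = 0.21 with an estimated correlation, 5 adjusted over the list alone). Members included the flight muscle troponin TpnC41C at 0.95 ± 0.17 and the myosin light chain Mlc1 at 0.79 ± 0.17. The complex IV median was 0.33 without high-fraction 0.25% YE replicate 1. The mitochondrial ribosomal median was 0.44 without high-fraction 4% YE replicate 1 and 0.16 without high-fraction 0.25% YE replicate 1. The muscle median was 0.21 without high-fraction 0.25% YE replicate 1.

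As deposited, where the median of all probe sets was 0.21, the synthetase and haemocyte medians were 0.03 and 0.04. Relative to all probe sets they were -0.18 and -0.17, in the direction of the normalized ones. After normalization, lists with smaller falls in the high fraction were lipid synthesis and storage (median -0.29, adjusted p = 0.006, and adjusted p = 0.21 with an estimated correlation), aminoacyl-tRNA synthetases (-0.21, adjusted p = 0.011, and adjusted p = 0.47 with an estimated correlation), fatty acid oxidation (-0.37, adjusted p = 0.012, and adjusted p = 0.23 with an estimated correlation), heat shock proteins (-0.33, adjusted p = 0.025, and adjusted p = 0.23 with an estimated correlation), haemocyte (-0.21, adjusted p = 0.025, and adjusted p = 0.39 with an estimated correlation), glycolysis (-0.12, adjusted p = 0.048, and adjusted p = 0.25 with an estimated correlation) and the citric acid cycle (-0.27, adjusted p = 0.048, and adjusted p = 0.35 with an estimated correlation), and noncoding RNAs rose (0.30, adjusted p = 0.006, and adjusted p = 0.47 with an estimated correlation). No member of these 8 lists was called over all genes, and adjusted over the list alone 2 lipid and 1 haemocyte mRNAs were lower. In replicates 2 and 3 alone, 14 of the 20 lists kept their call and direction. Without high-fraction 0.25% YE replicate 1 adjusted p was 0.0538 for muscle (range over its alternatives 5.3e-05 to 0.34), 0.096 for ATP synthase (range 0.00019 to 0.42), 0.0826 for mitochondrial import (range 0.00063 to 0.34), 0.0538 for heat shock (range 0.012 to 0.34), 0.0961 for fatty acid oxidation (range 0.0055 to 0.34), 0.0538 for synthetases (range 0.0015 to 0.47) and 0.108 for haemocyte (range 0.014 to 0.38). Without high-fraction 4% YE replicate 1 it was 0.187 for synthetases, 0.0535 for fatty acid oxidation, 0.166 for haemocyte and 0.299 for noncoding RNAs, which also lost the call without high-fraction 0.25% YE replicate 3 (0.125, range 0.00039 to 0.47). The heat shock call was also lost without high-fraction 4% YE replicate 3 (0.0567). The glycolysis call was lost without high-fraction 4% YE replicate 1 (0.202), low-fraction 4% YE replicate 1 (0.0583), 2 (0.0532) or 3 (0.0534), high-fraction 0.25% YE replicate 1 (0.205) or 3 (0.0696) or low-fraction 0.25% YE replicate 2 (0.0518), and the citric acid cycle call without high-fraction 4% YE replicate 1 (0.166) or 3 (0.0624), low-fraction 4% YE replicate 1 (0.0573), 2 (0.0506) or 3 (0.0527), high-fraction 0.25% YE replicate 2 (0.08) or 3 (0.291) or low-fraction 0.25% YE replicate 1 (0.0501) or 2 (0.0518). The digestive call was lost without high-fraction 0.25% YE replicate 3 (0.0555). With the replicate number as a block glycolysis was not called (adjusted p = 0.072, range 0.019 to 0.37) and neuron was (adjusted p = 0.031, against 0.068 without it). It had an adjusted p = 0.34 with the block and an estimated correlation. The haemocyte median was -0.13 without high-fraction 4% YE replicate 1. The glycolysis median was -0.06, -0.19 and -0.18 without high-fraction 4% YE replicates 1, 2 and 3 and -0.19 without high-fraction 0.25% YE replicate 2. The citric acid cycle median was -0.42, -0.14 and -0.14 without high-fraction 0.25% YE replicates 1, 2 and 3. The noncoding median was 0.10 without high-fraction 4% YE replicate 1 and 0.58 without high-fraction 0.25% YE replicate 1.

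In total 61 probe sets rose and 138 fell in the high fraction by limma, and 212 rose and 262 fell with the replicate number as a block. In replicates 2 and 3 alone 1293 rose and 1201 fell, without the excess of falls. The 199 calls dropped to 106, 62 and 61 without high-fraction 4% YE replicates 1, 2 and 3, to 128 and 123 without low-fraction 4% YE replicates 2 and 3 and to 86 without high-fraction 0.25% YE replicate 3, and rose to 508 without low-fraction 0.25% YE replicate 1. As deposited, 6 rose and 35 fell (14.6% higher against 30.7%). Calls of Lsp2, Mal-A4, Cyp309a1, Cyp12d1-d, GstD8, Amyrel, CG34316, CG3999, CG13215 and CG13947 held in each of the 12 omissions of 1 array. The fit call was lost without high-fraction 4% YE replicate 2 (0.08) or 3 (0.077), that of GstD4 without high-fraction 4% YE replicate 2 (0.052) or 3 (0.06), and that of Mal-A8 without high-fraction 4% YE replicate 2 (0.081) or 3 (0.068) or high-fraction 0.25% YE replicate 3 (0.055). The COX5B call was lost without high-fraction 4% YE replicate 2 (0.052) or 3 (0.064) or high-fraction 0.25% YE replicate 3 (0.062), and that of TpnC41C without high-fraction 4% YE replicate 3 (0.057) or high-fraction 0.25% YE replicate 3 (0.067). The Tsf1 call was lost without high-fraction 4% YE replicate 1 (0.077), 2 (0.094) or 3 (0.074), and that of RpL24-like without high-fraction 4% YE replicate 1 (0.071), 2 (0.055) or 3 (0.085). The ND-13A call held only without high-fraction 0.25% YE replicate 2 or low-fraction 0.25% YE replicate 1 (adjusted p elsewhere up to 0.15), that of Mlc1 only without replicate 1 of either fraction of 0.25% YE (up to 0.16), and that of Mal-A2 only without a low-fraction 0.25% YE array (up to 0.17). InR (0.64 ± 0.29), S6k (0.17 ± 0.35), foxo (0.28 ± 0.47) and eIF4E1 (0.19 ± 0.17) were not called (adjusted p = 0.36, 0.91, 0.88 and 0.74). Of the 20 lists called, 0 held with an estimated correlation by camera (6 at an unadjusted p under 0.05), and fry called 13.

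**Figure D2:**
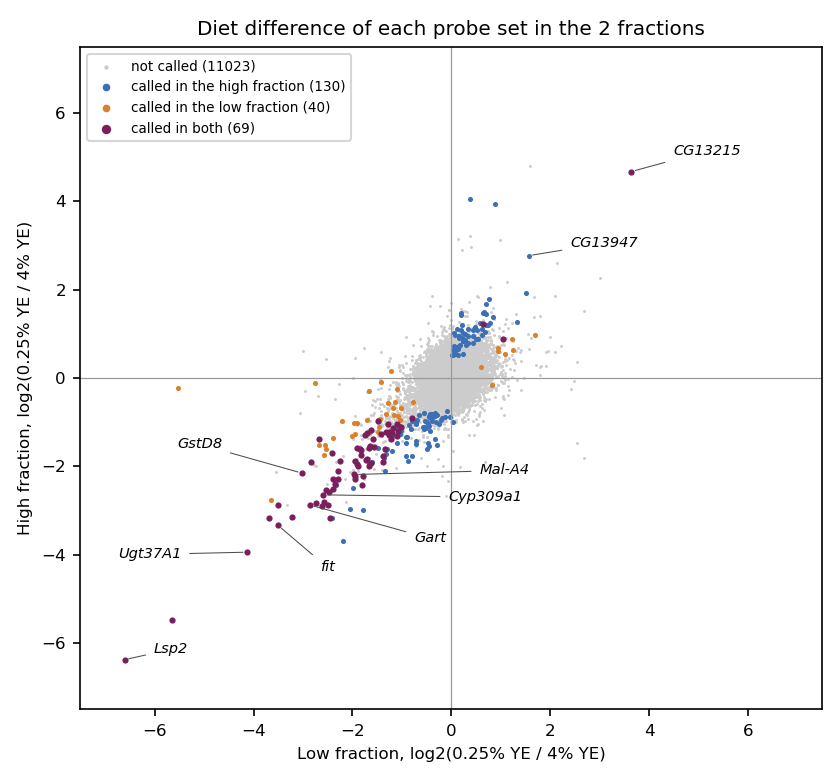
Log2 difference between diets (0.25% YE over 4% YE) of each of the 11262 probe sets in the low fraction (x axis) and the high fraction (y axis), coloured by where it was called, with 9 genes named. Lsp2 and fit lay low in both fractions and CG13215 high in both, and 66 probe sets were called lower in both.

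In the low fraction, too, the falls included fat body and detoxification genes. Genes of neither group also fell, among them CG15533 at -3.51 ± 0.53 and CG14957 at -2.84 ± 0.25. Lsp2 went from 4690 ± 323 to 60.2 ± 40.7 (-6.61 ± 0.77, adjusted p = 0.00091), and Gart, an enzyme of purine synthesis (1637037_at), from 721 ± 83.5 to 98.9 ± 16.2 (-2.86 ± 0.23, adjusted p = 0.00017). GstD8 (1634554_at) went from 385 ± 129 to 46.8 ± 17 (-3.02 ± 0.31, adjusted p = 0.00047). Rises were fewer, with CG13215 at 3.64 ± 0.35, the protease-like CG12374 at 1.70 ± 0.27 and the kinase anchor Akap200 at 1.25 ± 0.21. Glutathione S-transferases had 4 of 33 lower and 29 not called (median -0.71, adjusted p = 7.1e-16, and adjusted p = 0.39 with an estimated correlation, 13 lower adjusted over the list alone), and the median was -0.30 in replicates 2 and 3 alone. The glutathione S-transferase median was -0.23 without low-fraction 0.25% YE replicate 1.

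P450s had 4 of 72 lower and 68 not called (median -0.22, adjusted p = 4.2e-06, and adjusted p = 0.55 with an estimated correlation, 10 adjusted over the list alone). Among these was Cyp309a1 at -2.59 ± 0.23. Digestive enzymes had 2 of 30 lower (median -0.51, adjusted p = 1.8e-05, and adjusted p = 0.55 with an estimated correlation, 7 adjusted over the list alone), with Mal-A4 at -1.96 ± 0.25, but not without low-fraction 0.25% YE replicate 1 (adjusted p = 0.275, range over its alternatives 2e-11 to 0.66). The fat body list had 3 of 7 lower (median -1.0, adjusted p = 1.8e-05, and adjusted p = 0.14 with an estimated correlation, 3 adjusted over the list alone). Rising lists without a member called over all genes were muscle (median 0.35, adjusted p = 0.00017, and adjusted p = 0.14 with an estimated correlation), noncoding RNAs (0.26, adjusted p = 0.0016, and adjusted p = 0.55 with an estimated correlation, 4 adjusted over the list alone), photoreceptor (0.36, adjusted p = 0.0016, and adjusted p = 0.34 with an estimated correlation), testis (0.30, adjusted p = 0.003, and adjusted p = 0.55 with an estimated correlation) and neuron (0.23, adjusted p = 0.012, and adjusted p = 0.43 with an estimated correlation). Without low-fraction 4% YE replicate 1 adjusted p was 0.119 for noncoding RNAs (range 9.7e-05 to 0.66), 0.0572 for photoreceptor (range 0.00013 to 0.48), 0.282 for testis (range 2.4e-05 to 0.94) and 0.129 for neuron (range 0.0041 to 0.43). Without low-fraction 0.25% YE replicate 1 it was 0.14 for noncoding RNAs and 0.243 for testis, and without replicates 2 and 3 of that group it was 0.0691 and 0.0623 for neuron. Mitochondrial ribosomal proteins had a median of -0.21 (adjusted p = 0.0016, and adjusted p = 0.75 with an estimated correlation), which was 0.04 in replicates 2 and 3 and 0.04 without low-fraction 0.25% YE replicate 1 (adjusted p = 0.529, range 5.9e-07 to 0.81), with no member called. The P450 median was -0.13, -0.38 and -0.34 without low-fraction 4% YE replicates 1, 2 and 3. The digestive median was -0.32 without low-fraction 4% YE replicate 2 and -0.11 without low-fraction 0.25% YE replicate 1. The fat body median was -0.62 without low-fraction 0.25% YE replicate 1. The noncoding median was 0.12 and 0.48 without low-fraction 4% YE replicates 1 and 3. The testis median was 0.10 without low-fraction 4% YE replicate 1 and 0.15 without low-fraction 0.25% YE replicate 1. The neuron median was 0.46 without low-fraction 0.25% YE replicate 1. The mitochondrial ribosomal median was -0.40 without low-fraction 0.25% YE replicate 3.

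In all, 11 probe sets rose and 98 fell in the low fraction, and 51 and 203 with the replicate number as a block. Replicates 2 and 3 alone gave 398 rises and 498 falls. The 109 calls dropped to 72, 45 and 55 without low-fraction 4% YE replicates 1, 2 and 3 and to 52 without low-fraction 0.25% YE replicate 2. Calls of Lsp2, Gart, CG15533, CG14957, GstD8, Cyp309a1, Mal-A4 and CG13215 held in each of the 12 omissions, and those of CG12374 and Akap200 in all but that of low-fraction 0.25% YE replicate 2 (0.052 and 0.073). The insulin and TOR list was not called, but was with the replicate number as a block (adjusted p = 0.033, against 0.18 without it). It had an adjusted p = 0.36 with the block and an estimated correlation. InR, at 0.92 ± 0.29 (adjusted p = 0.23), was also called with that block (adjusted p = 0.014, range over its alternatives 7.3e-06 to 0.68), and S6k (0.54 ± 0.35), foxo (0.11 ± 0.47) and eIF4E1 (0.10 ± 0.17) were not called. The other 21 lists, complex I among them (median -0.02, or -0.27 with each array centred on its median, adjusted p = 0.87), were not called. Of the 10 called, 0 held with an estimated correlation by camera (3 at an unadjusted p under 0.05), and fry called 1. The high and the low fraction shared 66 falling probe sets (1.2 if independent) and 3 rising ones (0.0596 if independent).

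**Figure D3:**
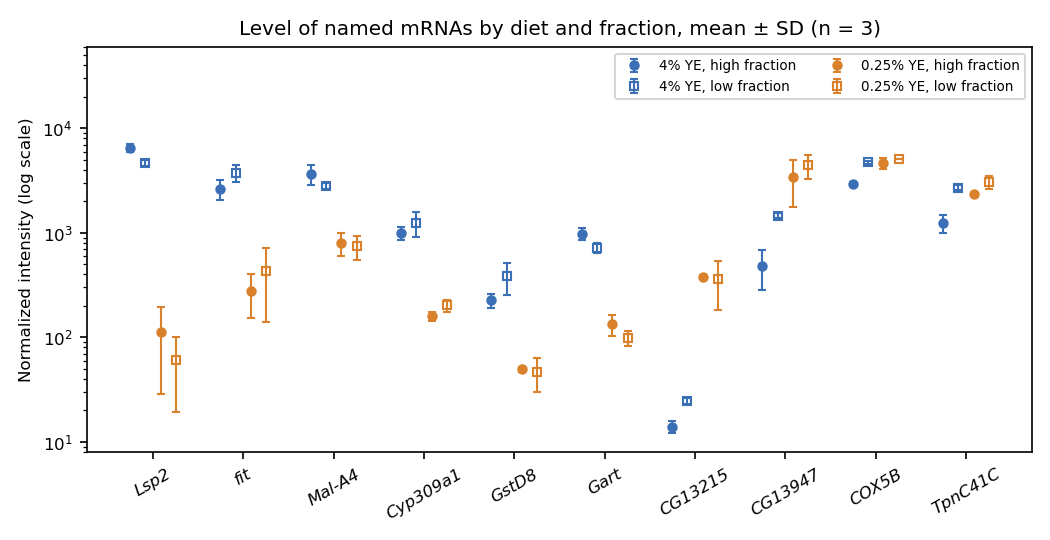
Normalized intensity (y axis, log scale) of 10 mRNAs (x axis) in each diet and fraction, with points for the mean and bars for SD (n = 3 arrays per group). Lsp2 averaged 6530 and 4690 on 4% YE against 112 and 60.2 on 0.25% YE, and CG13215 13.9 and 24.8 against 380 and 360.

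Averaged over both fractions, which stands in for the mRNA level since no unfractionated RNA was measured, the falls on 0.25% YE again included fat body, detoxification and digestive genes. Others were CG15263 at -3.42 ± 0.48, CG15533 at -3.19 ± 0.38 and CG34040 at -3.10 ± 0.51. Lsp2 changed by -6.49 ± 0.54 (adjusted p = 3.1e-05), fit by -3.42 ± 0.42, Gart by -2.87 ± 0.16, Cyp309a1 by -2.62 ± 0.16 and GstD8 by -2.59 ± 0.22. Npc2e, of a family of sterol-binding proteins, changed by -3.20 ± 0.45. Rises included CG13215 (adjusted p = 3e-06), whose size has no firm value since it was at background in the high fraction on 4% YE, CG13947 at 2.17 ± 0.25, the sugar-responsive transcription factor sugarbabe (sug) at 1.53 ± 0.27, the activin-like ligand dawdle (daw) at 1.60 ± 0.35 and the antimicrobial peptide Metchnikowin (Mtk) at 1.99 ± 0.45. The Mtk call was lost without high-fraction 4% YE replicate 2 (0.068) or 3 (0.075), low-fraction 4% YE replicate 2 (0.072) or 3 (0.071) or low-fraction 0.25% YE replicate 2 (0.055). The daw call was lost without high-fraction 4% YE replicate 2 (0.07) or 3 (0.065) or low-fraction 4% YE replicate 2 (0.072) or 3 (0.065). Glutathione S-transferases had 9 of 33 lower and 24 not called (median -0.46, adjusted p = 5.3e-11, and adjusted p = 0.28 with an estimated correlation, 12 adjusted over the list alone), P450s 13 of 72 (median -0.32, adjusted p = 1.3e-09, and adjusted p = 0.28 with an estimated correlation, 16 adjusted over the list alone) and the fat body list 3 of 7 (median -0.92, adjusted p = 6.9e-06, and adjusted p = 0.075 with an estimated correlation, 4 adjusted over the list alone). Digestive enzymes had 6 of 30 lower (median -0.19, adjusted p = 0.00033, and adjusted p = 0.46 with an estimated correlation, 9 adjusted over the list alone). Members included Mal-A4 at -2.07 ± 0.18 and Mal-A3 at -2.09 ± 0.39. The glutathione S-transferase median was -0.30 without low-fraction 0.25% YE replicate 1. The P450 median was -0.21 without low-fraction 4% YE replicate 1. The fat body median was -0.59 without low-fraction 0.25% YE replicate 1. The digestive median was -0.32 without high-fraction 4% YE replicate 3, -0.29 without low-fraction 4% YE replicate 3 and -0.08 and -0.33 without low-fraction 0.25% YE replicates 1 and 3.

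Muscle mRNAs had 3 of 23 higher (median 0.40, adjusted p = 1.8e-05, and adjusted p = 0.075 with an estimated correlation, 4 adjusted over the list alone). Among these was Mlc1 at 0.62 ± 0.12. With median centring complex I had a median of 0.03, complex IV 0.05, complex III 0.04 and mitochondrial import 0.20. After quantile normalization complex I had 0.24 (adjusted p = 5.2e-06, and adjusted p = 0.33 with an estimated correlation, 3 of 27 adjusted over the list alone), complex IV 0.26 (adjusted p = 0.0002, and adjusted p = 0.28 with an estimated correlation, 5 of 8), complex III 0.23 (adjusted p = 0.0054, and adjusted p = 0.28 with an estimated correlation, 3 of 7) and mitochondrial import 0.30 (adjusted p = 0.0041, and adjusted p = 0.28 with an estimated correlation, 5 of 12). Members included COX5B at 0.38 ± 0.08. Noncoding RNAs had 3 of 30 higher (median 0.31, adjusted p = 0.00064, and adjusted p = 0.43 with an estimated correlation, 5 adjusted over the list alone). Among these was lncRNA:CR31781 at 0.88 ± 0.16. Photoreceptor (median 0.24, adjusted p = 0.0064, and adjusted p = 0.28 with an estimated correlation) and neuron (0.30, adjusted p = 0.011, and adjusted p = 0.28 with an estimated correlation) mRNAs rose as lists. With median centring, cytosolic ribosomal protein and ATP synthase mRNAs had medians of -0.09 and -0.13. After quantile normalization they were higher by 0.11 and 0.11 (adjusted p = 0.0017 and 0.013, and adjusted p = 0.46 and 0.43 with an estimated correlation). Fatty acid oxidation (-0.26, adjusted p = 0.014, and adjusted p = 0.28 with an estimated correlation), the proteasome (-0.14, adjusted p = 0.028, and adjusted p = 0.59 with an estimated correlation) and haemocyte mRNAs (-0.22, adjusted p = 0.032, and adjusted p = 0.43 with an estimated correlation) were lower, with the prophenoloxidase PPO1 at -0.97 ± 0.15, and testis mRNAs were higher (0.12, adjusted p = 0.034, and adjusted p = 0.56 with an estimated correlation). The COX5B call was lost without low-fraction 4% YE replicate 2 (0.067), high-fraction 0.25% YE replicate 3 (0.055) or low-fraction 0.25% YE replicate 2 (0.053). The noncoding median was 0.17 without high-fraction 4% YE replicate 1 and 0.19 without low-fraction 4% YE replicate 1. The neuron median was 0.19 without high-fraction 4% YE replicate 1. The proteasome median was -0.05 without high-fraction 4% YE replicate 1 and -0.03 and -0.24 without low-fraction 0.25% YE replicates 1 and 3. The haemocyte median was -0.14 without high-fraction 4% YE replicate 1, -0.13 without low-fraction 4% YE replicate 1 and -0.14 without high-fraction 0.25% YE replicate 1. The testis median was 0.03 and 0.22 without low-fraction 4% YE replicates 1 and 3 and 0.18 without high-fraction 0.25% YE replicate 1. The cytosolic ribosomal median was 0.07 and 0.17 without high-fraction 0.25% YE replicates 1 and 2 and 0.07 without low-fraction 0.25% YE replicate 1. The ATP synthase median was 0.07 without high-fraction 4% YE replicate 2 and 0.18 and 0.07 without low-fraction 0.25% YE replicates 1 and 3.

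The averaged comparison called 138 probe sets higher and 327 lower, and 359 and 522 with the replicate number as a block. With only replicates 2 and 3, 1338 were higher and 1167 lower, without the excess of falls. The 465 calls dropped to 276 and 278 without high-fraction 4% YE replicates 2 and 3, to 261 and 299 without low-fraction 4% YE replicates 2 and 3, to 292 without high-fraction 0.25% YE replicate 3 and to 294 without low-fraction 0.25% YE replicate 2, and rose to 726 without low-fraction 0.25% YE replicate 1. As deposited 33 rose and 125 fell (20.9% higher against 29.7%, with a median of all probe sets of 0.18), and with median centring 84 rose and 366 fell (18.7% higher). The proteasome call was lost without high-fraction 4% YE replicate 1 (0.161), low-fraction 4% YE replicate 2 (0.103), high-fraction 0.25% YE replicate 1 (0.0525) or 3 (0.0954) or low-fraction 0.25% YE replicate 1 (0.407), with adjusted p from 0.00077 to 0.72 over its alternatives. The testis call was lost without high-fraction 4% YE replicate 1 (0.132), low-fraction 4% YE replicate 1 (0.268), high-fraction 0.25% YE replicate 3 (0.0952) or low-fraction 0.25% YE replicate 1 (0.274) (range 0.0044 to 0.72), and the haemocyte call without high-fraction 4% YE replicate 1 (0.093), low-fraction 4% YE replicate 1 (0.203), high-fraction 0.25% YE replicate 1 (0.0654) or low-fraction 0.25% YE replicate 3 (0.0857) (range 0.01 to 0.45). Without high-fraction 0.25% YE replicate 1 the ATP synthase and fatty acid oxidation calls were lost (0.122 and 0.0525, ranges 0.0032 to 0.77 and 0.0086 to 0.44). InR, at 0.78 ± 0.20, missed the threshold (adjusted p = 0.054) and passed it with the replicate number as a block (adjusted p = 0.0022, range over its alternatives 3.7e-06 to 0.15). S6k (0.36 ± 0.24, adjusted p = 0.55), foxo (0.20 ± 0.33, adjusted p = 0.84) and eIF4E1 (0.14 ± 0.12, adjusted p = 0.64) were not called. Of the 18 lists called, 0 held with an estimated correlation by camera (2 at an unadjusted p under 0.05), and fry called 9.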

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

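The tests on replicates 2 and 3 alone, on tissue content and on the fat body were chosen after the results were seen. Between the diets 1 transcript and 12 gene lists differed in their index by a test of the difference itself. The transcript was CG43131 (5.30 log2), with a low fraction at background on 0.25% YE. The medians of lists that rose were 0.30 for cytosolic ribosomal proteins, 0.46 for mitochondrial ribosomal proteins, 0.52 for complex I, 0.26 for complex III with cytochrome c, 0.45 for complex IV, 0.35 for ATP synthase and 0.52 for glutathione S-transferases. Those of lists that fell were -0.41 for the citric acid cycle, -0.17 for glycolysis, -0.23 for aminoacyl-tRNA synthetases, -0.31 for heat shock proteins and -0.29 for lipid synthesis and storage. Without low-fraction 0.25% YE replicate 1 the medians were 0.248 for mitochondrial ribosomal proteins, 0.211 for ATP synthase, 0.055 for glutathione S-transferases, -0.098 for synthetases, -0.168 for heat shock proteins and -0.14 for lipid synthesis and storage. Without high-fraction 0.25% YE replicate 1 that of complex I was 0.337. None of the 12 passed camera with an estimated correlation (0 of 31 lists, 6 at an unadjusted p under 0.05) or fry (0, with 7 at an unadjusted p under 0.05).

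The first pattern was the rise of the index of respiratory and ribosomal protein mRNAs on 0.25% YE. Weaker separation of the fractions would raise every mRNA with a low index. Against 10000 lists matched on the 4% YE index, the rise was at percentile 99.89 for complex I and 100 for mitochondrial ribosomal proteins. The matched ranges ended at 0.434 and 0.224 and were not redrawn without 1 array. For complex IV (90.25) and cytosolic ribosomal proteins (89.44) the rise lay within the range (medians 0.241 and 0.212). Percentiles ignore correlation within lists, so weaker separation stays open. In replicates 2 and 3 the medians were 0.325 for complex I, 0.333 for complex IV, 0.278 for mitochondrial and 0.239 for cytosolic ribosomal proteins. These were smaller, so the first gradient may supply part. A biological effect of the diet on translation of these mRNAs stays open, as a hypothesis found and tested on the same 6 gradients.

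The second pattern was that replicate 1 lay apart from replicates 2 and 3 in every group. If the boundary between the fractions had been set differently in replicate 1, its departure should follow the index of the other diet, but the 4 correlations were -0.278 and -0.122 in the high and low fraction on 4% YE and -0.407 and -0.0742 on 0.25% YE, all of the same sign, with the smallest at 0.0742 in size, which decides nothing. Different tissue content of its flies would move both fractions alike, and the departure differed between fractions by over 0.3 log2 in 2 of 8 tissue lists on 4% YE and in 5 of 8 on 0.25% YE, with digestive enzymes on 0.25% YE at -1.27 in the low and -0.01 in the high fraction. The 2 explanations cannot be told apart from each other or from a batch, since the labels give no dates. No biological explanation was tested, as the design names none for a replicate.

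The third pattern was the fall of fat body, glutathione S-transferase and P450 mRNAs on 0.25% YE. A smaller share of fat body tissue would lower its mRNAs alike, but Lsp2 fell by 6.49 log2 and fit by 3.42, and the median of the other 5 fat body list members was -0.37 (-1.07 to 0.25), which argues against it as the whole cause for Lsp2 and fit. For the wider fall it stays open, since 3 of 7 members fell by over 1 and 3 by no more than 0.5 or rose (apolpp -0.11, Apoltp 0.25, Treh -0.37). Other tissue lists moved in the average, none called with estimated correlation (medians muscle 0.395, neuron 0.30, photoreceptor 0.24, haemocyte -0.22). In replicates 2 and 3 the largest adjusted p of the 3 lists by camera was 9.72e-06, at the preset correlation. This does not decide the share of the first gradient. With an estimated correlation none of the 3 passed over all replicates (adjusted p = 0.0755 for fat body and 0.285 for the other two). A change of expression with the diet stays open as the biological explanation and was not tested apart from tissue content.

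Each contrast was also run with gradients or arrays exchanged between its groups, and with 10 splits a share under 0.05 cannot be reached. The real grouping gave 3846 calls for the index on 4% YE and 2409 on 0.25% YE (highest of the other splits 0 and 0), 1 for the index change (0), 199 and 109 for the diet in the high and low fraction (1 and 0) and 465 for the average (0), and in each 1 split of 10 gave as many, the real one. Called lists numbered 18 for the index on 4% YE (highest other 13), 20 for the diet in the high fraction (19) and 18 for the average (17), again with 1 split of 10 as high. For the index change 2 of 10 splits gave 12 lists, the real one and that which exchanged replicate 3 of 4% YE with replicate 2 of 0.25% YE.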

How the results depend on the processing

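The settings with replicates 2 and 3 only, replicate 1 as a batch, the filter on the mean of log2 values and the estimated correlation with a number block, and the list results of the index on 0.25% YE and of the low fraction, were added after the data were seen. The cause was not tested unless given. Of 290 called results of named genes over 7007 settings, 6245 kept their direction and side of the threshold, 762 lost the call and 0 reversed. Of 94 list calls over 1926 settings, 1574 were kept, 342 were lost and 10 reversed. The spread of the index differed between diets by -0.0593 to 0.0337, always within the spread between gradients.

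Requiring at least 2-fold gave 2395 and 1472 calls for the index on 4% and 0.25% YE and 210 for the average, by construction. As deposited, the counts were 2403, 1583, 41 and 42 for the high and low fraction and 158 for the average, with 9 lists for the average. For the index change the count was 4 without a filter, 0 with the lowest 60% left out, with log2(value + 32), with the filter on log2 means and with the number or gradient as a block, and 3 without the trend. The number block gave 3932 for the index on 0.25% YE, and 474, 254 and 881 for the high and low fraction and the average. The pairing changed no other call of a list or gene that the report names than those printed there. Fits of only the compared arrays, with fewer residual degrees of freedom, gave 386 for the index on 0.25% YE and 34 for the low fraction.

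Replicates 2 and 3 only gave 6950 and 6473 for the indices, 7 for the index change and 2494, 896 and 2505 for the diet contrasts, in that order (1293, 398 and 1338 higher). With replicate 1 as a batch there were 4352 for the index on 0.25% YE and 712, 374 and 1166. The weights of arrayWeights did not converge, with 48.4 on low-fraction 0.25% YE replicate 2, so its counts of 7700, 8851, 2914, 3915, 4115 and 4565 are not relied on. With an estimated correlation camera called 0 lists in each contrast, and 0 with the number block added (unadjusted counts in the report).

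Omitting 1 array gave 2614 to 4763 calls for the index on 4% YE, 752 to 3575 on 0.25% YE, 0 to 1 for the change, 61 to 508 and 45 to 148 for the high and low fraction and 261 to 726 for the average, with each array that moved a count named in the report. List counts were 17 to 19, 9 to 14 for the change, 14 to 22 for the high fraction and 15 to 18 for the average, and spread differences -0.0541 to 0.0337.

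Reversed medians as deposited were 0.028 for synthetases and 0.041 for haemocyte in the high fraction and 0.018 for the ATP synthase index on 0.25% YE. Relative to all probe sets they were -0.18, -0.17 and -0.39, in the direction of the normalized ones. In replicates 2 and 3 reversed medians were -0.092 for digestive enzymes and -0.234 for accessory gland in the high fraction, 0.002 for the averaged proteasome, -0.319 for the mitochondrial ribosomal index on 0.25% YE and 0.042 for that list in the low fraction. Digestive enzymes in the high fraction had -0.018 and -0.131 without high-fraction 4% YE replicate 1 and 3, and -0.164 and -0.039 without high-fraction 0.25% YE replicate 1 and 2 (highest of the omissions 0.023). Without high-fraction 0.25% YE replicate 1 accessory gland had -0.177 there (highest 0.209). Without low-fraction 0.25% YE replicate 1 the digestive index change was -0.179 (highest 0.501) and the mitochondrial ribosomal median in the low fraction 0.043 (lowest -0.402).

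The gradient cannot be a block for the diet contrasts, and fitting only the compared arrays changes nothing for the index change and the average. Probe sets above background, 59.0% to 66.4% per array, limit what could be tested. Of 101 results named for size, 28 had a group at background.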

Other observations

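These patterns were picked after their values were seen. Within the fat body list the drop on 0.25% YE was uneven: averaged over fractions, mean intensity went from 5610 to 86.2 for Lsp2, from 3190 to 353 for fit, from 5070 to 2460 for Tsf1 and from 6300 to 3740 for the odorant-binding protein Obp99b, while apolpp, the precursor of the main lipid carrier of the blood, was at 6120 and 5680. Lsp2 and fit thus dropped far more than apolpp, and this was not tested as a contrast of its own.

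In replicates 2 and 3 alone, Pdi had high- and low-fraction means of 765 and 154 on 4% YE against 130 and 135 on 0.25% YE (index change -2.39 ± 0.27, adjusted p = 0.015 by limma). Over all 3 replicates the change was -2.58 but was not called (adjusted p = 0.99 by limma).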
